A study of Mus musculus with 2 samples.

How the data were processed

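Gene expression was measured on Affymetrix arrays in epithelium isolated from ICR mouse fetal lung at embryonic day 11 and kept in a gel of basement membrane matrix. There were 2 arrays, 1 of epithelium cultured with CHIR99021 and 1 of epithelium cultured without it, so no spread between cultures could be measured and no test between the conditions was possible. Per the labels' protocols, 100 ng of total RNA was turned into biotinylated cRNA with a 3' in vitro transcription kit, which primes from the poly-A tail and therefore reads mostly the 3' ends of transcripts.

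The values deposited by the authors are MAS5 signal intensities per probe set on a linear scale, per the submitters' processing notes, which name MAS5 without a version or a scaling target. MAS5 subtracts mismatch signal, so the values of dim probe sets scatter widely, and no detection call was used here. The deposited intensity values were all positive and ran from 0.0201 to 14129 on the array without CHIR99021 and from 0.0232 to 13693 on the array with it. Their medians over probe sets other than controls were 32.9 and 20.3, and the 2% trimmed means over all probe sets were 204 and 151. The arrays had therefore not been brought to 1 common trimmed mean over all probe sets, and which scaling, if any, was applied stays unknown.

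Probe sets were named from the annotation of the array platform, whose symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6. Of 45101 probe sets, 64 were Affymetrix controls, 34958 named 1 gene (the named controls included), 932 named several genes and 9160 were not named here. Entrez identifiers of 34754 probe sets were found in the table, and 0 symbols needed a change. Genes were represented by the single-gene probe set with the highest mean log2 signal, which gave 18193 genes. Probe sets of several genes were not used. Gapdh had no single-gene probe set apart from the Affymetrix controls, and 12 of the 21 ribosomal protein genes in the list used here had one. No genome sequence was used and no coordinates are given.

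Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. A background floor was set for each array at the 95th percentile of its 80 probe sets for olfactory and vomeronasal receptor genes, which gave a signal of 19.2 without CHIR99021 and 12.7 with it. Values below the floor were raised to the floor, so that a ratio with 1 array below the floor is a bound, written as "at least". Log2 ratios are the array with CHIR99021 over the array without it, on the authors' scale. A gene counted as measured when it was above the floor on at least 1 array, and as higher or lower when the ratio reached 2-fold. The precision is limited by the number of arrays, 1 per condition. Among 5335 genes with 2 or more probe sets above the floor on both arrays, the log2 ratios of probe sets of the same gene had an SD of 0.557, which measures differences between probes and not between cultures.

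All 37 gene lists were fixed before the data were examined, as were the floor, the fold threshold and the rule for naming genes. Each list was summarised by the median log2 ratio of its measured members and by the percentile of that median among 10000 random gene lists of the same size, drawn from the same 20 bins of mean log2 signal. A list is said to stand apart when the percentile is under 5 or over 95. The percentile describes these 2 arrays only. Genes are named by this rule: the 12 highest and the 12 lowest log2 ratios among genes above the floor on both arrays, at 4 times the floor or more on the brighter one and with all probe sets above the floor agreeing in sign; the 5 brightest genes in each direction that were above the floor on 1 array only; up to 4 members per list with the largest change; and 23 genes fixed in advance (RIKEN clone names and unnamed loci passed over in the first pair of rules), of which Gapdh is given from its control probe sets. Genes outside this rule are marked as chosen after their values were seen.

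Alternatives were median centring of the probe sets above the floor, quantile and loess normalization (span 0.4), scaling on the 9 bacterial hybridization control probe sets with r2 in their names (chosen after seeing the data), other floors or none, an offset of 16 before the log, the median over a gene's probe sets, leaving out probe sets with the suffixes _x_at and _s_at, fold thresholds of 1.5 and 3, the mean in place of the median of a list, and random lists not matched on signal. The procedure was tested on simulated data drawn from the real signals of 18193 genes. The simulation was easier than the data, so its rates are not rates for these arrays. Only bright genes were changed, and the shift was the same at every signal. Noise was the same for all probe sets and smaller than the SD of 0.557 between real probe sets of a gene. With 200 genes changed and an overall shift of the size seen here, 79.4% of genes changed by 1.5 on the log2 scale and 98.1% of those changed by 2 were called on the authors' scale, and 94.8% and 100% after median centring. Of 12234 unchanged genes 1.98% were called on the authors' scale and 0.0409% after median centring. Of 300 simulated lists with no change 9.67% stood apart, and 100% of 100 lists shifted by 0.5 did.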

Results

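The study asked how gene expression in fetal lung epithelium depends on CHIR99021, an inhibitor of glycogen synthase kinase 3 that stabilises beta-catenin and so switches on canonical Wnt signalling. Epithelium of embryonic day 11 was first grown for 4 days in Matrigel, a basement membrane gel, with CHIR99021 and FGF10, the growth factor that drives lung budding. It was then broken into fragments, embedded again and grown for 2 more days with FGF10, either with CHIR99021 kept in the medium or without it. Both cultures had thus seen the inhibitor, and the comparison is between its continued presence and its withdrawal. Each condition was measured on 1 array, so every value below is a single measurement, no error between cultures can be given and no p-value was computed.

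Of 18193 genes on the array, 12917 were above the background floor on at least 1 array and 11356 on both. Across the latter, the log2 signals of the arrays correlated with r = 0.93, across genes, which are not independent replicates. Most genes were dimmer on the array with CHIR99021: the median log2 ratio was -0.40, and 76.4% of genes had a lower signal there. The 9 bacterial hybridization control probe sets with r2 in their names, whose RNA is added after labelling, had a median log2 ratio of -0.17, and all 18 of both designs one of -0.15. The ratio of 3' to 5' signal of beta-actin was 1.29 without CHIR99021 and 3.18 with it, and that of Gapdh, a glycolytic enzyme used as a control, was 0.737 and 1.62. Spiked bacterial poly-A transcripts were divided: dap went the same way with 3.58 and 9.07 and so did thr with 2.60 and 5.38, while lys (1.12 and 1.02) and phe (2.43 and 2.06) did not. Every comparison below sets the array with the larger 3' bias of beta-actin and Gapdh against the other. The median gene lay at -0.40, but bright genes shifted less than dim ones, so it is no fixed baseline for log2 ratios. For Actb, at a signal of 9012 without CHIR99021, loess changed the log2 ratio only from -0.02 to -0.03. For Axin2, at 58.2, it changed from 2.20 to 2.74.

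**Figure D1:**
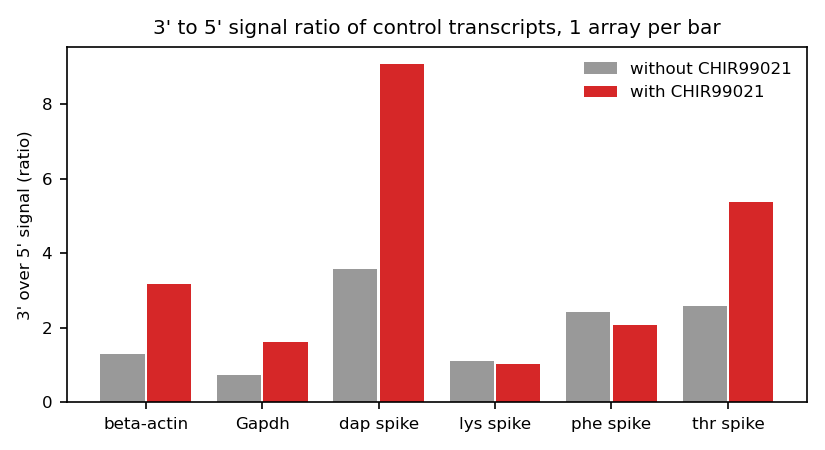
Ratio of 3' to 5' signal (vertical axis, linear ratio) of 2 mouse transcripts and 4 spiked bacterial transcripts, with 1 bar per array, grey without and red with CHIR99021. The ratio of beta-actin was 1.29 without and 3.18 with CHIR99021, and that of the dap spike was 3.58 and 9.07.

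On the authors' scale, 245 genes were at least 2-fold higher and 2380 at least 2-fold lower with CHIR99021. Of these, 46 and 416 were above the floor on 1 array only, so their ratios are bounds. The floor was 19.2 without and 12.7 with CHIR99021, so such a gene had to be brighter to count as higher than as lower. Without a floor 1213 were higher and 4606 lower. The split depends on the scaling as well. Higher genes made up 9.33% of the calls on the authors' scale, 59.2% after median centring (1110 higher and 764 lower), 53.5% after quantile normalization (954 and 829), 45.3% after loess (779 and 942) and 16.7% when scaled on the hybridization controls (354 and 1765). Relative to the median gene on the authors' scale, 633 genes were at least 2-fold higher and 1116 lower. Median centring was done on probe sets and shifted the log2 ratios by 0.62, more than the median gene's difference. The log2 ratio of the median gene was 0.22, 0.12, 0.05 and -0.24 after these scalings, in the same order. The medians of the 19 lists that stood apart had the same sign under all 4 of them as on the authors' scale. Among genes with a further probe set above the floor on both arrays, that probe set had the same sign for 82.8% of 87 higher and 97.6% of 829 lower genes. Since 76.4% of genes above the floor on both arrays were lower, the same sign is easier to reach for lower genes. Among genes named below as past 2-fold, some had a further probe set above the floor on both arrays that was not. Its log2 ratio was 0.50 for Nkd1, 0.16 for Lamb1, 0.43 for Fst, -0.20 for Wnt7a, -0.30 for Rhoa, -0.84 for Vangl1, -0.98 for Me1, -0.33 for Mvk and -0.56 for Klf6. Of the 37 gene lists, 7 stood above and 12 below expression-matched random lists, where 3.7 would be expected outside these limits by chance. That number holds for lists of genes that vary independently, while members of these lists can vary together and some lists share genes.

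**Figure D2:**
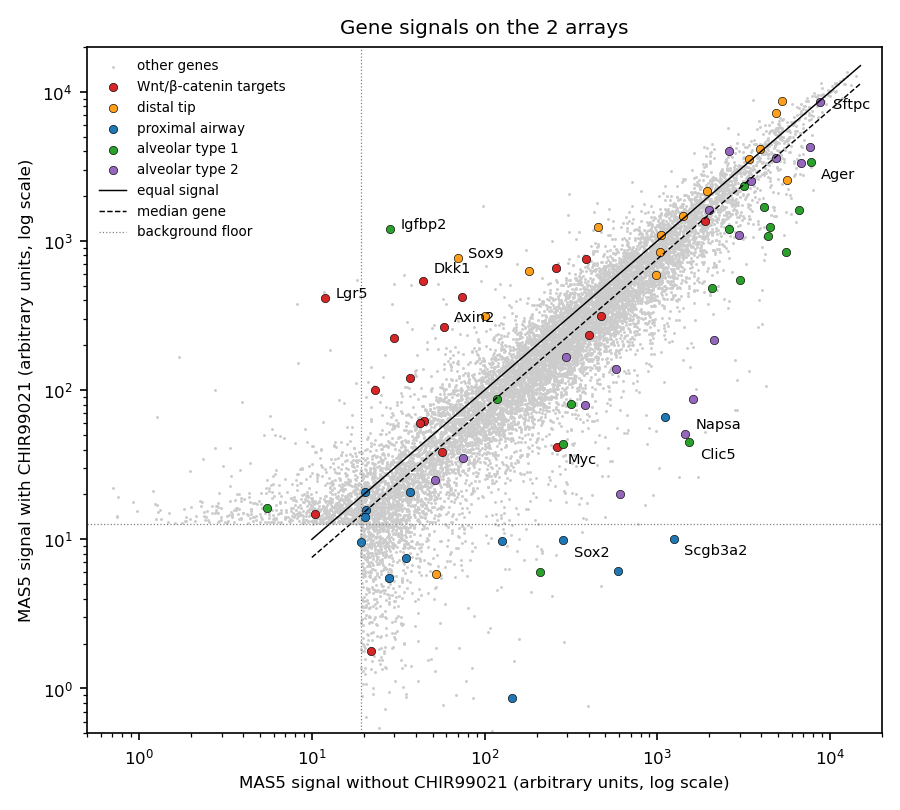
MAS5 signal of each measured gene without CHIR99021 (horizontal axis) and with it (vertical axis), both in arbitrary units on log scales, with 1 point per gene, 5 marker lists in colour and the genes of lowest signal outside the axes. Solid and dashed lines mark equal signal and the median gene (log2 ratio -0.40), and dotted lines mark the background floors; Lgr5, Dkk1, Sox9 and Igfbp2 lie far above the lines, and Scgb3a2, Sox2, Clic5 and Napsa far below.

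Target genes of Wnt and beta-catenin signalling stood above matched random lists, with 8 of 18 measured members at least 2-fold higher with CHIR99021. Lgr5, a Wnt-amplifying receptor and stem cell marker, was at a signal of 416 with CHIR99021 and below the floor without it, a difference of at least 21.7-fold. Dkk1, a secreted Wnt antagonist, was 12.2-fold higher (541 against 44.3), Lef1, a DNA-binding partner of beta-catenin, 7.57-fold (225 against 29.8), and Axin2, a feedback inhibitor of the pathway, 4.59-fold (267 against 58.2). Sp5, a transcription factor, was 4.34-fold higher and Nkd1, a feedback regulator, 3.26-fold. Notum, a secreted enzyme that inactivates Wnt ligands, had signals of 44.8 without and 62.5 with CHIR99021, under the 2-fold threshold. Myc went the other way and was 6.32-fold lower (41.5 against 263). In the list 9 targets were within 2-fold and 1 was lower, and after median centring 11 were higher and 1 lower. Their median log2 ratio was 0.75, against -0.47 for matched random lists, at percentile 100, and it stayed at percentile 100 under every alternative run.

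The genes that encode Wnt ligands, receptors and transducers did not move together. Wnt7b, a ligand of the distal lung epithelium, was 3.47-fold higher with CHIR99021 (629 against 181). Wnt5a, a mostly non-canonical ligand, was 9.85-fold lower (29.6 against 292), Wnt7a 5.53-fold lower and Wnt4 3.82-fold lower, and Wnt9a was at 71.1 without CHIR99021 and below the floor with it, at least 5.58-fold lower. Of 33 measured members 1 was higher and 11 lower (4 and 6 after median centring), and the median lay at percentile 45.4.

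Markers of the distal lung tip, the progenitor domain of the branching epithelium, stood above matched random lists. Sox9, the transcription factor that marks the tip, was 11.0-fold higher with CHIR99021 (771 against 70.1). Cxcr4, a chemokine receptor, was 3.14-fold higher. Wnt7b, also in this list, was 3.47-fold higher. Some other tip genes were under the 2-fold threshold. Bmp4, a growth factor of the bud tip, had 3911 without and 4126 with CHIR99021, and Etv5, a target of FGF signalling, 1050 and 1105. Id2, an inhibitor of differentiation factors, had 4855 and 7265. Its log2 ratio of 0.58 was 1.20 after median centring and 0.64 after loess. Probe sets of Etv5 (the others at log2 ratios of -1.11 and -1.57) and of Id2 (lowest -0.11) disagreed in sign. Shh, the Hedgehog ligand made by lung epithelium, was 2.21-fold lower with CHIR99021 (2557 against 5662), with a dimmer probe set at 285 without and 14.8 with the inhibitor. Fgfr2, the FGF10 receptor, had 989 without and 595 with CHIR99021, and 382 and 78.7 by its other probe set above the floor. Nkx2-1, the lung identity factor, was read by 1 dim probe set, at 52.0 without CHIR99021 and below the floor with it. Of 15 measured members 4 were higher and 2 lower (6 and 1 after median centring). The median log2 ratio was 0.08 against -0.25 for random lists, at percentile 98.9, and the percentile was 84.3 when the median over all probe sets of a gene was used.

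Markers of the proximal airway were lower with CHIR99021. Sox2, the transcription factor of the conducting airway, had a signal of 285 without CHIR99021 and was below the floor with it, at least 22.4-fold lower. Scgb3a2, a secretoglobin of airway secretory cells, was at least 98.0-fold lower (1247 without), and Cyp2f2, a cytochrome P450 of club cells, at least 46.5-fold lower (591 without). Aldh1a1, a retinaldehyde dehydrogenase, was 16.8-fold lower (65.7 against 1107). Of 13 measured airway and secretory genes 0 were higher and 8 lower (0 and 6 after median centring), with a median log2 ratio of -1.47 at percentile 0. These values come from the array whose 3' to 5' ratio of beta-actin was 3.18, as do those of the alveolar, junction and lipid genes below. The list of basal cell genes, the stem cells of the airway, moved the same way, with 5 of 8 measured members lower and 0 higher (4 and 1 after median centring), at percentile 0.02, or 7.85 without a floor. Among them Aqp3, a water channel, was 21.1-fold lower, Krt15, a keratin, at least 6.70-fold lower, and Trp63, the basal cell transcription factor, at least 4.42-fold lower. Ciliated cell genes did not stand apart (percentile 48.5), with 1 of 9 measured members higher and 2 lower (1 and 0 after median centring). Of 12 neuroendocrine genes with a probe set only 2 were measured (percentile 16.9), of which Ddc was 2.63-fold lower and Uchl1 had 42.8 without and 28.4 with CHIR99021.

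Alveolar genes were lower with CHIR99021 as well, and by the median the alveolar type 1 list had the lowest ratio of all lists. These cells form the thin gas exchange surface. Clic5, an intracellular chloride channel protein, was 34.4-fold lower (44.7 against 1536), Aqp5, a water channel, at least 16.4-fold lower, S100a6, a calcium-binding protein, 6.56-fold lower, Pdpn, a surface glycoprotein, 6.47-fold lower, and Vegfa, an endothelial growth factor, 4.34-fold lower. The exception was Igfbp2, a binding protein of insulin-like growth factors, which had the highest ratio of the named genes above the floor on both arrays, 42.3-fold higher with CHIR99021 (1209 against 28.5). Of 17 measured type 1 genes 1 was higher and 13 lower (1 and 10 after median centring), with a median log2 ratio of -1.98 against -0.25, at percentile 0.

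Genes of alveolar type 2 cells, which make surfactant, were lower in part. Il33, a cytokine, was 30.4-fold lower (609 without), Napsa, an aspartic protease that processes surfactant protein, 28.5-fold lower (51.1 against 1456), Sftpd, surfactant protein D, 18.3-fold lower (87.8 against 1602), and Slc34a2, a phosphate transporter, 9.83-fold lower (218 against 2142). Sftpc, surfactant protein C, was among the brightest genes and had nearly equal signals, 8808 without and 8500 with CHIR99021, while its other probe set, near the floor, had 30.5 and 16.2. Sftpb and Sftpa1, further surfactant genes chosen after their values were seen, differed less than Sftpd: the former had 6828 without and 3312 with CHIR99021, and the latter 1998 and 1611, with its other probe set at a log2 ratio of -1.45. Of 17 measured type 2 genes 0 were higher and 10 lower (1 and 6 after median centring), with a median log2 ratio of -1.05 at percentile 0.01.

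**Figure D3:**
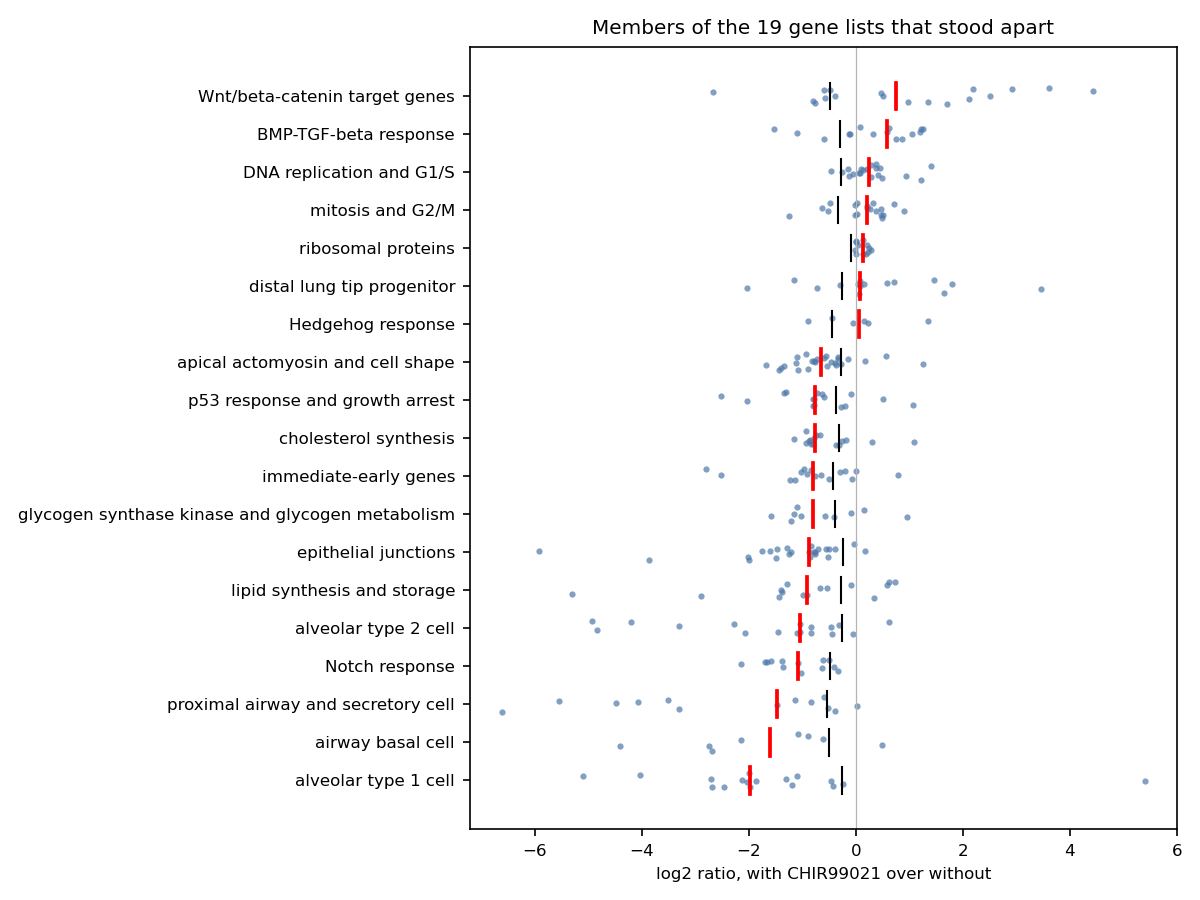
Log2 ratio of each measured member (points, horizontal axis, with over without CHIR99021, values below the floor raised to it) of the 19 lists outside the 5th to 95th percentile of random lists. Red bars are the list medians and black bars the medians of matched random lists; the Wnt targets have the highest median, 0.75, and alveolar type 1 genes the lowest, -1.98.

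Epithelial junction genes stood below matched random lists, with part of them at least 2-fold lower with CHIR99021. Among junction and keratin genes, Dsc2, a desmosomal cadherin, was 60.4-fold lower (12.8, just above the floor, against 771), Krt19, a keratin of simple epithelia, 14.5-fold lower (278 against 4030), Pkp1, a desmosomal plaque protein, at least 4.04-fold lower, and Cldn18, a lung tight junction protein, 4.01-fold lower. Epcam, an epithelial adhesion molecule, had 3846 without and 3743 with CHIR99021, and Cdh1, E-cadherin, 6414 and 3574. Of 24 measured junction genes 0 were higher and 11 lower (0 and 5 after median centring), at percentile 0. In the list of apical actomyosin and cell shape genes, Rhoa, a GTPase that controls actomyosin contraction, was 3.20-fold lower, Shroom3, a scaffold of apical constriction, 2.70-fold lower, Vangl1, a planar polarity protein, 2.64-fold lower and Myh14, a non-muscle myosin, 2.52-fold lower. Of its 26 measured members 1 was higher and 7 lower (2 and 1 after median centring). The list lay at percentile 0.47, which became 23.7 with the median over all probe sets and 5.22 against random lists not matched on signal.

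The list of cell polarity and microtubule regulators did not stand apart (percentile 8.45, but 4.17 after quantile normalization and 4.38 after loess), with 1 of 26 members higher and 6 lower (2 and 1 after median centring). The higher one was Mark1, a kinase of microtubule-associated proteins, with a signal of 124.5 with CHIR99021 and 49.0 without, 2.54-fold. Prkcz, an atypical protein kinase C, was 4.60-fold lower, Pard6b, its polarity partner, 2.71-fold lower and Dlg1, a basolateral scaffold, 2.49-fold lower.

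Cell cycle genes stood above random lists of like signal, with mostly small differences between the arrays. Uhrf1, which maintains DNA methylation during replication, was 2.67-fold higher (2160 against 810), though its other probe set had 126 without and 143 with CHIR99021, and Gins2, a subunit of the replicative helicase, 2.34-fold higher. Ung, a DNA repair enzyme, had 194 without and 371 with CHIR99021. Of 20 measured replication and G1/S genes 2 were higher and 0 lower (7 and 0 after median centring), and 19 lay above the median of random lists. Their median log2 ratio was 0.25 at percentile 100. For the 19 measured mitosis genes it was 0.22, also at percentile 100, with 0 higher and 1 lower (6 and 0 after median centring). Kif20a, a mitotic kinesin, was the lower one, at 2.39-fold, and Ccna2, cyclin A, had 920 without and 1717 with CHIR99021, with probe sets that disagreed in sign. In the list of p53 response and growth arrest genes, Btg2, an antiproliferative factor, was 5.76-fold lower, Cdkn2b, an inhibitor of cyclin-dependent kinases, 4.08-fold lower and Cdkn1c, another such inhibitor, 2.54-fold lower. Cdkn1a, the p21 inhibitor and a p53 target, named after its value was seen, was 2.11-fold higher, with its other probe set at a log2 ratio of 0.25. Of 16 measured members 1 was higher and 4 lower (2 and 2 after median centring), at percentile 1.30, or 6.5 by the list mean.

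Signalling lists differed in direction. The BMP and TGF-beta list stood above random lists, with a median log2 ratio of 0.58 at percentile 100 and 4 of 15 members higher and 2 lower (8 and 0 after median centring). Msx1, a BMP-induced transcription factor, was 2.38-fold higher and Fst, an activin antagonist, at least 2.29-fold higher. Msx2 was 2.34-fold higher, but its log2 ratio was -0.01 as the median of its probe sets. Id4, a further target, was 2.87-fold lower. Notch genes were lower: Nrarp, a feedback inhibitor, 4.41-fold, Dll1, a ligand, 3.25-fold, Hes1, a target transcription factor, 3.14-fold and Heyl, a further target, at least 2.99-fold. Of 13 measured Notch genes 0 were higher and 8 lower (0 and 3 after median centring), at percentile 0.29. The FGF and ERK list did not stand apart (percentile 51.8), but lay at 1.40 with the median over probe sets. In it Etv4, a transcription factor induced by FGF, was 4.32-fold higher, though its other probe set had 58.4 without and 62.5 with CHIR99021, while Ier3, an immediate-early gene, was 7.26-fold lower, Dusp4, a MAP kinase phosphatase, 3.34-fold lower and Spry1, a feedback inhibitor, 2.20-fold lower, giving 1 higher and 4 lower of 11 (2 and 2 after median centring). The Hedgehog list lay at percentile 97.6 with 1 of 6 members higher, Gli3, a transcription factor, at 2.56-fold, and at 91.0 without a floor or 93.2 with an offset. Immediate-early genes lay at percentile 2.22, with 0 higher and 5 lower of 16 (1 and 2 after median centring), Fos 6.95-fold lower and Klf6 2.34-fold lower.

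Lipid genes were lower in part. Cd36, a fatty acid transporter, was 39.4-fold lower with CHIR99021 (73.5 against 2895), Pparg, a lipogenic nuclear receptor, 7.41-fold, Gpam, an enzyme of triglyceride synthesis, 2.69-fold and Me1, malic enzyme, 2.62-fold. Of 15 measured lipid genes 0 were higher and 6 lower (3 and 2 after median centring), at percentile 0.10. The cholesterol synthesis list lay at percentile 0.64 with 1 member higher and 1 lower of 16 (1 and 0 after median centring). Dhcr7, the enzyme of its last step, was 2.12-fold higher and Mvk, mevalonate kinase, 2.23-fold lower. That percentile became 9.73 with the median over probe sets and 18.5 by the list mean. The glycogen list lay at percentile 3.42, with 5 of 10 members lower, Pygb, a glycogen phosphorylase, by 3.01-fold, but 0 lower after median centring and a percentile of 5.48 or more under 6 of the alternatives. Ribosomal protein genes had a median log2 ratio of 0.14, at percentile 98.0, with 0 of 12 past 2-fold. Their percentile was 63.0 after quantile normalization and 87.0 after loess. Rps19, for example, had 8976 without and 10652 with CHIR99021.

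Basement membrane genes moved both ways. Nid2, nidogen 2, was 17.3-fold higher with CHIR99021 (519 with), Lamb1, a laminin beta chain, 6.71-fold higher (2057 against 306) and Lama3, a laminin alpha chain, 3.49-fold higher, while Fras1, a basement membrane protein of budding epithelia, was 3.80-fold lower. Of 19 measured members 3 were higher and 6 lower (5 and 1 after median centring), and the median lay at percentile 27.9, and the list mean at 97.9. Genes of epithelial-mesenchymal transition lay at percentile 15.7, but at 0.99 after quantile normalization, 0.69 after loess and 0.92 with the median over probe sets, with 1 of 9 higher and 4 lower (1 and 1 after median centring). Fn1, fibronectin, was 4.05-fold higher, S100a4 5.06-fold lower and Zeb2, a transcription factor, 3.01-fold lower, and Vim, vimentin, had 257 without and 245 with CHIR99021.

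Lists for cells that could have been carried over from the dissected lung did not stand apart on the authors' scale with the main settings. The percentiles were 78.3 for mesenchyme and smooth muscle, 66.1 for endothelium (97.3 without _x_at and _s_at probe sets), 68.5 for blood and immune cells, 7.0 for mesothelium and 28.4 for neural cells. Many of their genes were not measured: 11 of 21 mesenchymal, 7 of 15 endothelial, 4 of 14 blood and 6 of 10 mesothelial genes with a probe set were above the floor, as were 5 of 9 neural ones. At least 2-fold lower were 1 mesenchymal, 1 endothelial, 1 blood, 3 mesothelial and 0 neural genes, and 0 were higher. After median centring 1 mesenchymal and 1 endothelial gene were higher, and 1 blood gene and 2 mesothelial genes lower. The lower endothelial gene was Egfl7, whose log2 ratio was 0.23 without _x_at and _s_at probe sets. The mesenchymal, endothelial and mesothelial lists each share 1 gene with another list, which for the last is Krt19. Col1a1, the main fibroblast collagen, had 24.7 without and 35.8 with CHIR99021. Msln, mesothelin, was the brightest mesothelial marker apart from Krt19, with 471 without CHIR99021 and a value below the floor with it, at least 37.0-fold lower, and the mesothelial list lay under percentile 5 in 5 of the alternatives. Genes of other endodermal organs lay at percentile 86.7, but at 0.45 with the floor at the array median and 0.44 with the floor doubled. Afp, alpha-fetoprotein, was 3.84-fold lower with CHIR99021 (241 against 928), Alb, albumin, at least 8.25-fold lower and Hhex, a transcription factor of foregut endoderm, 2.63-fold lower, and of the 13 measured genes 4 were lower and 0 higher (2 and 0 after median centring). The remaining lists were the YAP response (percentile 8.53, and 0.84 to 4.21 in 4 of the alternatives, 2 of 12 lower), retinoic acid response (6.39, and 0.22 to 4.58 in 7 of the alternatives, 3 of 5 lower, among them Rarb, a retinoic acid receptor, 9.47-fold), glycolysis and hypoxia (41.6, 6 of 20 lower, among them Ndrg1 6.71-fold), interferon response (11.7, 3 of 14 lower) and the unfolded protein and heat shock response (32.1, 1 of 18 lower). None of these had a member at least 2-fold higher on the authors' scale. After median centring, 2 genes of the retinoic acid, glycolysis and interferon lists each were lower, 0 of the YAP and unfolded protein lists, and 1 gene each of the glycolysis, interferon and unfolded protein lists was higher.

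Outside the lists, the named genes above the floor on both arrays with the highest ratios were Mia, a secreted protein, 17.4-fold higher (1710 against 98.3), Stc1, stanniocalcin 1, a secreted hormone, 17.3-fold, Ccdc80, a matrix protein, 13.7-fold, Fam89a 13.0-fold, Tent5a, a poly-A polymerase, 9.51-fold, Ppargc1a, a coactivator of mitochondrial biogenesis, 8.06-fold, and Ramp1, a receptor-modifying protein, 7.12-fold. Apoe, apolipoprotein E, had 379 with CHIR99021 and was below the floor without it, at least 19.8-fold higher, and Ankrd34b and Lin7a were at least 28.4-fold and at least 23.7-fold higher. Among the lowest ratios, Sec14l3 was 65.3-fold lower (26.3 against 1717), Cavin2, a caveolar protein, 50.6-fold, Krt79, a keratin, 50.5-fold, Il18r1, an interleukin 18 receptor chain, 47.5-fold, Akr1c14, a hydroxysteroid dehydrogenase, 39.9-fold, S100g, a calcium-binding protein, 38.1-fold, Gstm1, a glutathione transferase, 35.8-fold, Dock8 35.1-fold and Gkn2, gastrokine 2, 33.9-fold. Cyp2s1, a cytochrome P450, and Liph, a lipase, were above the floor only without CHIR99021, at least 31.1-fold and at least 28.7-fold lower. Actb, beta-actin, had 9012 without and 8889 with CHIR99021, and the control probe sets of Gapdh had log2 ratios of 0.47 at the 3' end and -0.67 at the 5' end.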

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

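All tests reported in this part were chosen after the values they use had been seen. What drew attention was signal outside the gene comparisons: control probe sets that differed from the array without CHIR99021, and probe sets without a single gene name.

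The array with CHIR99021 had lower signals for most genes and a larger 3' bias in some of the control transcripts. The ratio of 3' to 5' signal was 3.18 for beta-actin, 1.62 for Gapdh and 9.07 for the dap spike, against 1.29, 0.737 and 3.58 without CHIR99021. Lower brightness of the whole array at hybridization or scanning was set against the bacterial hybridization control probe sets. The 9 with r2 in their names had a median log2 ratio of -0.17 (SD 0.11, range -0.34 to 0.01), above the -0.3 set for such a cause. Of the 18 of both designs (median -0.15, lowest -0.41), 17 lay above the median gene at -0.40. The comparison cannot decide the question, because bright genes shifted less than dim ones and these controls were bright. Without CHIR99021 the r2 controls had signals of 327 to 11772, against a median of 32.9 over probe sets. Lower brightness therefore stays open. Shorter labelled RNA is a candidate explanation, on which the controls were divided. The 5' signal was lower relative to the 3' signal in beta-actin and Gapdh, by at least 1.13 on the log2 scale (Gapdh, log2 -1.13). The mouse 18S control had log2 ratios of -1.43 at the 3' end and -3.21 at the 5' end. It is a ribosomal RNA, which priming from the poly-A tail is not meant to read, so it cannot decide the question. Pyruvate carboxylase (-0.67 and -0.17) and the transferrin receptor (-1.93 and -0.11) went the other way from beta-actin, with 5' signals near the floor. Of the transcripts added from outside the cells, dap and thr went with beta-actin, and lys and phe did not. Whether shorter RNA accounts for the whole shift stays open, since the positions of the other probe sets along their transcripts were not used here. No biological explanation was tested.

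Airway, alveolar type 1 and alveolar type 2 markers were lower with CHIR99021 (47 measured genes, median log2 ratio -1.45). An intensity-dependent loss of signal on that array is argued against, because after loess their median was still -1.12, against 0.04 with an SD of 0.08 for matched random lists. These lists had already stood below random lists matched on signal, so the loess result adds little to that comparison. A lower share of epithelial cells was set against the distal tip list, which lay 1.52 above these markers, against an SD of 0.16 for random lists of its size. With the median over probe sets the values were 1.24 and 0.17, and the tip list itself lay at percentile 84.3. The gap cannot decide the question, because the lists had already been seen to lie apart. The tip list also holds genes that were higher, such as Sox9 (log2 ratio 3.46), so it is no neutral measure of epithelial share. Genes of the junction list moved apart, with log2 ratios of -0.04 for Epcam, -0.84 for Cdh1, -2.0 for Cldn18 and -3.86 for Krt19. Of these, Cldn18 is also in the alveolar type 1 list and Krt19 in the mesothelial list. A lower epithelial share should also lower Epcam as much as the airway and alveolar markers, and raise the lists of other cell types. Neither was seen with the main settings. Epcam was at -0.04 against -1.45, and those lists lay between percentiles 7.0 (mesothelium) and 78.3 (mesenchyme). However, Epcam is 1 gene, and many genes of the other cell types were below the floor. The junction list lay at percentile 0, so a lower share of epithelial cells stays open. An effect of the presence or absence of CHIR99021 is the explanation the design names and stays untested, since with 1 culture per condition it cannot be told apart from a difference between these particular cultures.

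Of 10092 probe sets without a single gene name 4834 were above the floor on at least 1 array, and of these 42 were at least 2-fold higher with CHIR99021 and 941 at least 2-fold lower, on the authors' scale. Of the 12917 measured genes 245 were higher and 2380 lower. The lower share was thus similar, and the count shows nothing particular to probe sets without a single gene name.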

How the results depend on the processing

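With 1 array per condition no replicate could be left out. No paired analysis was possible because each condition has 1 array and the labels give no replicate numbers. Only the scaling on hybridization controls was chosen after seeing the data. The counts of genes at least 2-fold higher and lower, 245 and 2380 on the authors' scale, were 1110 and 764 after median centring, 954 and 829 after quantile normalization, 779 and 942 after loess, 1213 and 4606 with no floor, 652 and 5005 at 1.5-fold, and 81 and 812 at 3-fold. They were within 1.5 times of the main counts under the other 6 alternatives. The median log2 ratio of the Wnt targets, 0.75, was 1.37 after median centring, 1.32 after quantile normalization, 1.24 after loess, 1.16 with the floor at the array median or doubled, 0.52 with no floor or with the median over probe sets, 0.37 with the offset and 0.92 as a mean, at percentile 100 in each. The number of lists that stood apart, 19, ranged from 17 to 22, and 11 of the 19 did so under every alternative, while 0 crossed from one side to the other and 9 of the other 18 stood apart in at least 1 alternative. Of 133 named genes past 2-fold, 131 kept their direction throughout and 44 were under 2-fold in at least 1 alternative. The direction changed for Msx2, with a log2 ratio of -0.0118 as the median over probe sets, and for Egfl7, an endothelial gene, with 0.23 when _x_at and _s_at probe sets were left out; the cause was not tested. Signals near the floor limit the folds: genes with a value below it have bounds, and those just above it, such as Dsc2, have folds that depend on the floor.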

Other observations

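All but 1 of the tests in this part were chosen after the values they use had been seen; the exception is the comparison of Y-linked genes with matched random lists.

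Gene families defined only by the stem of their symbols gave further groups. Of 216 families with 8 or more measured members, 7 lay under percentile 1 and 10 over percentile 99 of expression-matched random lists. By chance 2.16 would be expected on each side if members of a family varied independently. The families and the members named here were chosen after their values were seen. Annexins, calcium-dependent membrane-binding proteins, were lower with CHIR99021 in 7 of 8 measured members, with a median log2 ratio of -1.72 (4 lower and a median of -1.10 after median centring). Anxa3 was 5.19-fold lower (814 against 4221), Anxa1 3.63-fold (2193 against 7970) and Anxa8 at least 5.49-fold, while Anxa6 had 126 without and 84.4 with CHIR99021. Anxa2 was 4.92-fold lower, but another of its probe sets had a log2 ratio of -0.03. Keratins were lower in 15 of 24 members, Parp genes in 6 of 11 and genes with the stem Il, a mix of interleukins and their receptors, in 15 of 36, with 0 higher in each. After median centring 4 keratins, 3 Parp genes and 8 Il genes were lower, and 1 keratin and 1 Il gene higher. Wnt ligand genes, 7 of 12 lower and 1 higher (4 and 1 after median centring), had a median log2 ratio of -1.14. The other families under percentile 1 were Fbxo, with 8 of 28 lower and 0 higher (1 and 2 after median centring), and Snx, with 7 of 28 lower and 0 higher (3 and 1). The medians of these 7 families stayed below 0 under median centring, quantile normalization, loess and scaling on hybridization controls.

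The 10 families over percentile 99 had the stems Cep, Dennd, Gng, Lsm, Mrps, Nup, Sh, Snhg, Timm and Zfp. The Lsm genes of RNA processing complexes had a median log2 ratio of 0.28 over 12 members, the Snhg genes, hosts of small nucleolar RNAs, 0.44 over 13, with Snhg5 2.20-fold higher, the Nup genes of the nuclear pore 0.07 over 18 and the Timm genes of mitochondrial import 0.11 over 14. The 306 Zfp genes, many of them zinc finger genes, had a median of -0.31, which was above 0 after median centring, quantile normalization and loess and -0.14 when scaled on hybridization controls. The medians of the Lsm, Snhg, Nup and Timm genes were above 0 under all 4 scalings. Their place above random lists is relative to the medians of matched random lists, which were -0.35, -0.34, -0.35 and -0.32 in the same order.

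The Y-linked genes were lower with CHIR99021, with log2 ratios of -1.75 for Eif2s3y (179 against 603), -1.41 for Uty and -1.34 for Kdm5d. The array-wide loss of signal is argued against as the whole cause, since their median of -1.41 lay more than 2 SD below matched random lists (median -0.45, SD 0.43 for lists of 3 genes). A smaller share of male embryos in that culture is a candidate explanation: all 3 genes lay at least 0.93 below the median gene (highest, -0.93), and the brightest Xist probe set lay 0.84 above it. That probe set was bright, with 4452 without and 6011 with CHIR99021, and bright genes shifted less than dim ones. The median gene is thus no fixed baseline for it, and 0.84 may overstate its excess. The explanation rests on few genes, and the Xist probe sets disagreed, with log2 ratios of 0.43, 1.77 and -0.66.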
